A study of Drosophila melanogaster with 4 samples.

How the data were processed

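The 4 libraries were ChIP-seq libraries of nuclei from wild-type Oregon-R larvae in the third instar, 2 precipitated with an antibody to H3K23ac and 2 inputs, grouped by their titles. Each input served as the control of the ChIP replicate with the same number, per the labels. Per the labels' protocols, tissue was homogenised and fixed with formaldehyde, and chromatin was sheared by sonication before precipitation on protein A beads. Reads were aligned with Bowtie 0.12.7, per the submitters' processing notes. The 3 deposited lists hold regions of significant enrichment in FlyBase release 5 with the lengths of its sequences, per the file headers. One list belongs to each ChIP replicate and one to the replicate set of both. The peak caller, its threshold, read filters and the way in which replicates were combined for the set are not given in the sources used here. No list of the input libraries was used here. The number of regions that pass a significance threshold depends on depth and on the efficiency of the precipitation, so list lengths are not amounts of H3K23ac.

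The only measured value per cluster is a score that the authors deposited, whose scale no header states. It was examined in the values themselves. Scores were above 0 in each list, and 2 raised to the score matched a constant times a ratio of 2 whole numbers (denominator up to 2000, relative tolerance 1e-11) for 99.98% of clusters in replicate 1, 99.91% in replicate 2 and 98.43% in the replicate set, with constants of 0.555, 0.562 and 0.559. After a random shift of the scores by up to 1e-06 at most 0.0085% matched. The score was therefore read as the log2 of a scaled ratio of whole numbers. The lowest-terms denominator of that ratio is a lower bound on the number the authors divided by, which no source names, and it was used only in the closing observations. There, X and autosomal clusters under 2000 bp wide were also compared within score classes of 0.05 from 0.4 to 0.8 with at least 10 clusters on each side, with class ratios averaged on a log scale and weighted by the clusters on X, and likewise for clusters near the telomeres. Intervals of these ratios came from 2000 bootstrap resamples of clusters. Scores were used to describe, rank and filter clusters within a list and to correlate paired clusters between replicates.

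Read totals were not given in the sources used here, so depth is unknown and its contribution to the difference between the replicate lists was not separated. Exact binomial (Clopper-Pearson) 95% intervals are given for shares of clusters and cover counting error only. Nothing in the labels says that the replicates came from separate cultures or animals, so the spread between them may be technical. No p-value here measures spread between replicates. Those from circular shifts measure coincidence of positions along the chromosomes. The others measure spread between clusters, bins or arms of these libraries.

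Values were computed with Python 3.11.15, numpy 2.4.6 and scipy 1.17.1. Coordinates are 1-based as deposited. Covered sequence is the union of clusters, and arm lengths came from the deposited lists' headers. Overlap meant at least 1 shared bp. Overlap of the replicates was compared with 1000 circular shifts of one list, each chromosome shifted by its own random distance, one-sided, which keeps widths and spacing but moves clusters into cluster-free sequence too. For score agreement each cluster of replicate 1 was paired with the replicate 2 cluster sharing most bp. The share of the set's clusters found in a replicate was compared by score class with 1000 circular shifts that moved both replicate lists together. Differences between shared and replicate-only clusters were compared with 1000 circular shifts of the other list as well. Medians of shared and replicate-only clusters, of X and autosomal clusters, and correlations were tested with 100000 two-sided permutations, with Benjamini-Hochberg adjustment within each family. The ratio of X to the autosomal arms and its counterpart for chromosome 4 were given per replicate without a test across replicates. Overlap and whole-number matching were tested on simulated data, where 712 of 712 planted overlaps among 1200 clusters and 2000 of 2000 whole-number ratios were recovered, and 0 of 2000 shifted scores were taken for a ratio. The simulated denominators were all smaller than the median of 247 behind the replicate set's scores below 1. The simulation therefore does not show that such larger denominators are recovered.

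The groups, tests, alternatives and the rule for named regions were fixed before the data were examined. Without a gene annotation of the deposited build, that rule names by coordinates the 5 highest-scoring and the 5 widest clusters of the replicate set on the major arms, and the highest-scoring and the widest cluster of each arm. Other regions in the text were chosen after their values were seen. The alternatives fixed in this way were overlap of at least 50% of the smaller cluster, of the set's cluster or reciprocally, the better-scored 50% of each list, the major arms only, correlations within each arm, clusters per Mb, the replicate set and each replicate left out. Comparisons of 1 Mb bins, arm ends, cluster-free stretches, X scores and widths, the shifts behind shared and replicate-only clusters and behind the set's score classes, and a score of at least 0.6 or a width of at least 3000 bp were added after the data were seen. Enrichment at promoters, distribution over gene features and tests of gene lists had been planned (3 results), but the gene table at hand is of release 6 and the clusters of release 5, and coordinates were not converted, so these were not run and no genes are named.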

Results

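H3K23ac, an acetylated lysine in the tail of histone H3, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in nuclei of wild-type Oregon-R Drosophila melanogaster at the third larval instar. Acetylated histone tails are generally found in open and transcribed chromatin. The series held 4 libraries. In 2 of them the chromatin had been precipitated with an antibody to H3K23ac (ChIP replicates 1 and 2), and the other 2 were inputs, chromatin DNA sequenced without precipitation. Each input was the control of the ChIP library with its number, per the labels. How the authors' enrichment call used it is not given in the sources used here. The data analysed here were 3 lists of clusters, which are regions of significant H3K23ac enrichment: one for each ChIP replicate and one for the replicate set, with coordinates in FlyBase release 5. Read totals were not given in the sources used here, so the depth of each library is unknown. The questions the design poses are where in the larval genome H3K23ac was enriched, and whether both replicates placed it in the same regions. The position of the clusters within genes was not analysed here.

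H3K23ac clusters were numerous and short in both replicates, and replicate 2 held many more of them. Replicate 1 had 6267 clusters covering 12.6 Mb, or 10.5% of the 5 major chromosome arms (2L, 2R, 3L, 3R and X). Replicate 2 had 11757 clusters covering 30.0 Mb, or 25.2% of these arms. The mean was 9012 ± 3882 clusters (SD, n = 2) and 21.3 ± 12.3 Mb (SD, n = 2), and replicate 2 exceeded replicate 1 by 1.88-fold in number and 2.39-fold in covered sequence. The replicate set was larger than either, with 17999 clusters covering 49.8 Mb, or 41.7% of the major arms. Median cluster width was 1703 bp in replicate 1, 1956 bp in replicate 2 and 1911 bp in the replicate set. The widest clusters spanned 15763, 25496 and 41893 bp, respectively. The narrowest cluster of each replicate was 1301 bp wide, whereas that of the replicate set was 1001 bp wide, and 4110 clusters of the set were narrower than any cluster of a replicate. The authors' score, whose scale was read from its values as log2, had a median of 0.55 in each replicate and 0.39 in the replicate set, or 1.46, 1.46 and 1.31 as ratios under that reading. With 2 replicates no test between them was possible.

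Most regions called in replicate 1 were called again in replicate 2. Of the 6267 clusters of replicate 1, 5111 (81.6%, 95% exact binomial interval 80.6 to 82.5) overlapped a cluster of replicate 2 by at least 1 bp. In the other direction, 4692 of 11757 clusters of replicate 2 (39.9%, interval 39.0 to 40.8) overlapped one of replicate 1. The regions called in both came to 5538 stretches with a median of 1506 bp, spread over 9.22 Mb of the 33.4 Mb that either list covered, a Jaccard index of 0.276. In values computed after the data were seen, 25.3% of replicate 2's clusters on X and 42.3% of those on 2L, 2R, 3L and 3R overlapped replicate 1, with Jaccard indices of 0.164 and 0.293. X held less covered sequence, and circular shifts of one list within each chromosome gave mean overlaps of 10.7% on X and 23.6% on the autosomal arms, with Jaccard indices of 0.0401 and 0.0903. Relative to these means the overlap was 2.36-fold on X and 1.79-fold on the autosomal arms, and the Jaccard index 4.08-fold and 3.24-fold. The difference between X and the autosomal arms was not tested.

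Each overlap exceeded all 1000 circular shifts. For the whole genome the shifts averaged 41.0% of replicate 1's clusters, 21.7% of replicate 2's and a Jaccard index of 0.084, with highest values of 47.3%, 24.5% and 0.105. The one-sided permutation p from the shifts was 0.001 for each, the smallest that 1000 shifts can give. Under a reciprocal overlap of at least 50% the shares fell to 42.7% and 22.8%, which was also above all shifts.

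Clusters found in both replicates were wider and scored slightly higher than those found in a single replicate, by more than chance overlap gave on average. In replicate 2 the median width was 2566 bp for the 4692 shared clusters and 1738 bp for the 7065 others, a difference of 828.5 bp. In replicate 1 it was 1769 bp for 5111 shared clusters and 1512 bp for 1156 others, a difference of 257.5 bp. Median scores differed by 0.041 in replicate 2 and by 0.014 in replicate 1. Across the 5111 overlapping pairs the scores of the replicates were weakly correlated, with Spearman's rho of 0.31 and Pearson's r of 0.334, and r was 0.332 without the 2 most extreme pairs. The correlation was present on each arm, from a rho of 0.225 on X to 0.353 on 2R. Permutation tests with 100000 resamples gave two-sided p = 1e-05, the smallest they can give, for both widths, the score of replicate 2 and all 8 correlations computed, and p = 3e-05 for the score of replicate 1. After Benjamini-Hochberg adjustment the largest of these was 3e-05. A wide cluster meets another list more often by chance, so the differences were also compared, after the data were seen, with 1000 circular shifts of the other list. The shifts gave mean width differences of 95.8 bp in replicate 1 and 221.5 bp in replicate 2, with highest values of 158.5 and 356 bp. Mean score differences were 0.0030 and 0.013. The highest score difference of the shifts was 0.0145 in replicate 1, above the observed 0.0138, and 0.0246 in replicate 2, below the observed 0.041. With a reciprocal overlap of at least 50% the highest was 0.0177 in replicate 1, above the observed 0.0147 (two-sided p from the shifts 0.011). In replicate 2 it was 0.0047, below the observed 0.0077. The two-sided permutation p from the shifts was 0.001 for both widths and the score of replicate 2, the smallest possible, and 0.0020 for the score of replicate 1 (0.0020 at most after Benjamini-Hochberg adjustment over the 4). Clusters are not independent replicates. With a reciprocal overlap of at least 50% the differences were 301 bp and 0.0077 in replicate 2 (permutation p = 0.0158 for the score) and 279.5 bp and 0.015 in replicate 1, and rho was 0.44, whereas rho was 0.188 in the better-scored 50% of each list.

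The replicate set took in nearly everything found in either replicate and added many narrow, low-scoring regions. It overlapped 6233 of the 6267 clusters of replicate 1 (99.5%, exact interval 99.2 to 99.6) and 11600 of the 11757 clusters of replicate 2 (98.7%, interval 98.4 to 98.9). Conversely, 3929 of its 17999 clusters (21.8%, interval 21.2 to 22.4) overlapped a cluster in both replicates, and 10932 (60.7%, interval 60.02 to 61.45) did so in at least 1 replicate. The remaining 7067 clusters (39.3%) overlapped neither replicate. Those found in both had a median width of 4519 bp and a median score of 0.46, and those found in neither 1285 bp and 0.36. The narrowest cluster was 1001 bp wide in the set and 1301 bp in each replicate. Among set clusters with scores below 1, 467 of 4084 narrower than 1301 bp (11.4%) had a counterpart in a replicate. Of the 13884 at least that wide, 10464 (75.4%) had one. The share without a counterpart therefore depended strongly on width, and the score classes that follow were not separated by this width. The share with a counterpart in a replicate was 40.0% for scores under 0.3 (median width 1455 bp) and 92.2% for scores from 0.6 to 0.7 (5533 bp). It was 34.6% of 26 clusters with scores from 0.8 to 1 (1178 bp) and 1 of 31 clusters (3.23%, interval 0.082 to 16.7) with scores of at least 1 (1015 bp). Wide clusters meet other lists more often by chance, and 1000 circular shifts of both replicate lists together, run after the data were seen, gave means of 42.3%, 57.5%, 36.2% and 29.7% in these 4 classes. The observed share lay within the range of the shifts for scores under 0.3 (38.9 to 45.8%) and from 0.8 to 1 (7.69 to 65.4%), above it from 0.6 to 0.7 (highest 67.1%) and below it for scores of at least 1 (lowest 9.68%). When at least 50% of the set's cluster had to be covered, the share found in both replicates was 10.9%. Intervals here cover counting error only.

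**Figure D1:**
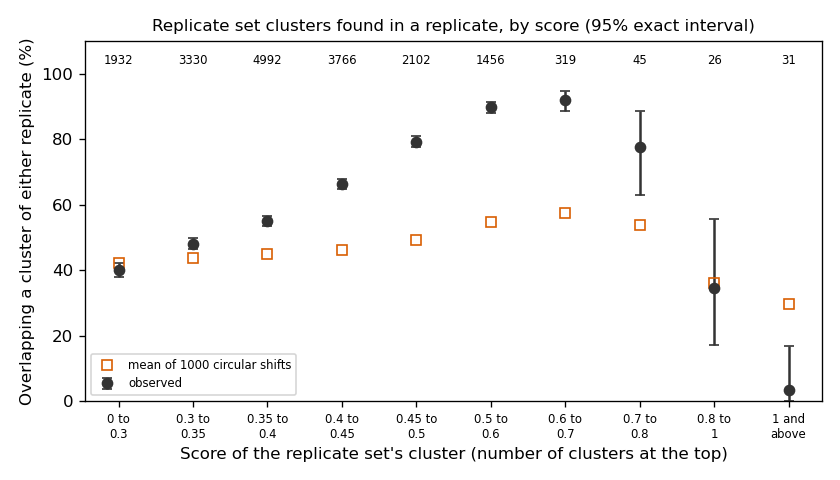
Share of the replicate set's clusters that overlapped a cluster of at least 1 replicate (y axis, percent) in classes of the authors' score (x axis, log2 scale); filled points are shares, bars are 95% exact binomial intervals, open squares are means of 1000 circular shifts of the replicate lists, and the number of clusters stands above each class. The share was 40.0% in the lowest class, 92.2% for scores from 0.6 to 0.7 and 3.23% for scores of at least 1, and the shifts gave 42.3%, 57.5% and 29.7%.

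The widest H3K23ac clusters of the replicate set overlapped clusters of both replicates, but as several separate clusters each. The widest, for instance, held 10 clusters of replicate 1 and 3 of replicate 2. The set is not independent of the replicates, so overlap with them is partly built in. The widest cluster of the replicate set lay between positions 448528 and 490420 of 3L (41893 bp, score 0.56), of which clusters of replicate 1 covered 62.6% and those of replicate 2 covered 89.5%. It was followed by 2R 3038264 to 3073934 (35671 bp, score 0.59), 3L 22365612 to 22401032 (35421 bp, score 0.58), 2R 20722466 to 20756950 (34485 bp, score 0.74) and 3L 22407882 to 22440622 (32741 bp, score 0.52). Over these 4 regions replicate 1 covered 51.4%, 61.3%, 75.01% and 55.7%, and replicate 2 covered 95.9%, 98.2%, 96.8% and 90.3%. The widest clusters of the other arms were 2L 5119120 to 5145358 (26239 bp), 3R 6375352 to 6404960 (29609 bp) and X 1185284 to 1204954 (19671 bp). Replicate 1 covered 79.4%, 62.7% and 37.2% of them, and replicate 2 covered 87.0%, 97.8% and 93.8%.

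The 5 clusters with the highest scores, by contrast, were narrow and none overlapped a cluster of either replicate. They lay at 3L 22796858 to 22797872 (score 3.33), 2L 20309140 to 20310140 (3.16), 3R 1984314 to 1985314 (3.16), X 13999380 to 14000384 (3.16) and 2R 14375372 to 14376372 (2.97). Their widths were 1001 to 1015 bp, which is under the 1301 bp minimum of the replicate lists. Each was also the highest score of its arm. What the genome annotation holds at these positions was not analysed here.

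Called H3K23ac clusters were spread over the large autosomal arms, were sparser on X and were few on chromosome 4. In replicate 1 clusters covered 11.2% of 2L, 12.5% of 2R, 11.02% of 3L and 12.5% of 3R, but 4.98% of X and 1.83% of chromosome 4. In replicate 2 the same values were 23.9%, 30.9%, 24.4% and 29.3% for the autosomal arms, 17.0% for X and 1.36% for chromosome 4, the small chromosome rich in heterochromatin. Over both replicates coverage was 17.6 ± 8.96% on 2L, 21.7 ± 13.0% on 2R, 17.7 ± 9.42% on 3L, 20.9 ± 11.9% on 3R, 10.99 ± 8.49% on X and 1.59 ± 0.332% on chromosome 4 (SD, n = 2 for each). The heterochromatic and unplaced sequences, which differ widely in length, held few clusters. Replicate 1 had 2 on U and 1 on XHet, and replicate 2 had 5 on U. The replicate set had 14 on U, 6 on XHet, 2 on 3RHet and 1 on 2RHet. None of the 3 lists had any on 2LHet, 3LHet, YHet or Uextra. In the set XHet was covered to 3.47% and chromosome 4 to 4.43%. How well short reads map to these sequences was not analysed here, so few clusters do not show that H3K23ac is absent there.

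**Figure D2:**
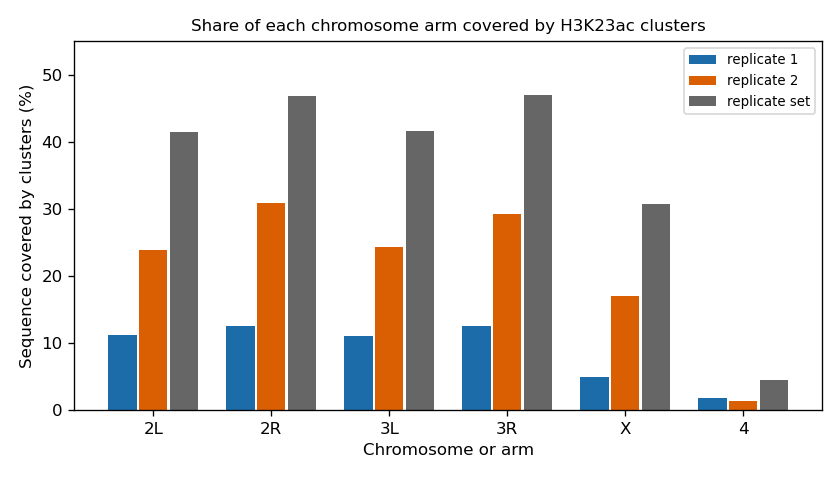
Share of each chromosome arm covered by H3K23ac clusters (y axis, percent) for the 5 major arms and chromosome 4 (x axis) in replicate 1, replicate 2 and the replicate set; each bar is the value of 1 list, without error. X lay below the 4 autosomal arms in each list, at 4.98%, 17.0% and 30.8%, and chromosome 4 lay lowest.

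The ratio of coverage on X to that on the 4 autosomal arms was 0.422 in replicate 1 and 0.627 in replicate 2. The mean was 0.525 ± 0.145 (SD, n = 2), so this ratio lay below 1 by more than its SD. It was 0.695 in the longer replicate set. Coverage itself differed more between the replicates: X in replicate 2 (17.0%) exceeded 2R and 3R in replicate 1 (12.5% each). For chromosome 4 the ratios were 0.155 and 0.0501, a mean of 0.102 ± 0.0739 (SD, n = 2), which rests on 14 and 10 clusters. It was 0.0364 in the better-scored 50% of each list. In a comparison added after the data were seen, the 22 full 1 Mb bins of X averaged 5.05 ± 2.54% in replicate 1 and 17.1 ± 8.40% in replicate 2, and the 95 autosomal bins 11.8 ± 4.80% and 27.1 ± 9.71% (SD over bins). The differences were -6.77 and -9.94 percentage points (two-sided permutation p = 1e-05 and 3e-05, 2e-05 and 3e-05 after Benjamini-Hochberg adjustment over both). Bins of a library are not independent replicates.

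The clusters that X did hold scored higher than those of the autosomal arms. Median scores on X and on the autosomal arms were 0.63 and 0.54 in replicate 1, 0.62 and 0.54 in replicate 2, and 0.43 and 0.38 in the replicate set. They were also narrower on X, with median widths of 1618 and 1711 bp in replicate 1, 1908 and 1966 bp in replicate 2, and 1755 and 1947 bp in the replicate set. The direction of the X difference therefore depended on the score. With all clusters kept, the number per Mb on X relative to the autosomal arms was 0.476 in replicate 1 and 0.696 in replicate 2, but with scores of at least 0.6 it was 1.46 (401 clusters on X and 1184 on the autosomal arms) and 1.48 (962 and 2802). For clusters at least 3000 bp wide the mean ratio was 0.323. Permutation tests of the medians, chosen after the data were seen, gave p = 1e-05 for the 3 score differences, the smallest possible with 100000 resamples. For width the permutation p was 0.00188, 0.0230 and 1e-05, and the largest p over the 6 tests after Benjamini-Hochberg adjustment was 0.0230.

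**Figure D3:**
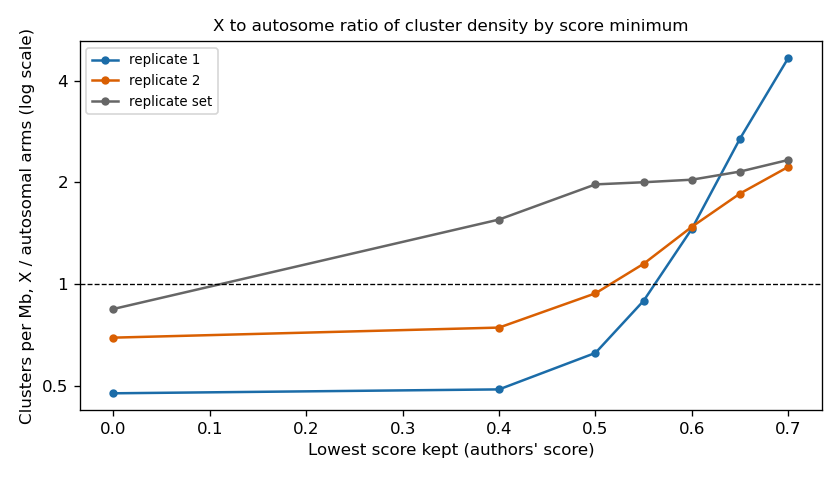
Clusters per Mb on X divided by clusters per Mb on the 4 autosomal arms (y axis, log scale) against the lowest authors' score kept (x axis, log2 score), for each replicate and the replicate set; points are single values without error and the dashed line marks a ratio of 1. With all clusters kept the ratio was 0.476, 0.696 and 0.845, and with scores of at least 0.6 it was 1.46, 1.48 and 2.04.

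Along the arms, megabases with high cluster coverage in one replicate tended to have high coverage in the other. Coverage in the 117 full 1 Mb bins was correlated between replicates across bins (Spearman's rho 0.881, Pearson's r 0.903, 0.893 without the 2 most extreme bins), also within the 95 autosomal bins (rho 0.828, r 0.896) and the 22 X bins (rho 0.868, r 0.937, 0.847 without the 2 most extreme). The bin from 20000001 to 21000000 of 2R was 27.0% covered in replicate 1 and 56.2% in replicate 2. The first megabase of 3L reached 27.4% and 46.3%, and that of 2L 22.2% and 45.2%. The bin from 22000001 to 23000000 of 3L, beside the cluster-free stretch at the centromere, reached 19.0% and 46.8%. The bin from 1000001 to 2000000 of X had the second-highest coverage of replicate 2, 46.9%, but only 13.1% in replicate 1. The 3 bin correlations were chosen after the data were seen (permutation p = 1e-05 each, the smallest possible), and bins are not independent replicates.

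The megabase next to the telomere was covered more than the rest of the arm on 5 of 5 arms in each list, as on 2R with 27.0% against 11.8% in replicate 1 and 51.6% against 29.8% in replicate 2. Single megabases elsewhere exceeded it on some arms. Counted from the telomere, the second megabase of X was higher in each list (13.1%, 46.9% and 60.4%, against 7.37%, 24.7% and 41.9% in the first), and the telomeric megabase was the highest of its arm on 3 of 5 arms in replicate 1 and on 2 of 5 in replicate 2. The mean difference over arms was 10.4 ± 6.19 percentage points in replicate 1, 18.0 ± 6.45 in replicate 2 and 16.7 ± 4.08 in the replicate set (SD, 5 arms). Without the cluster-free sequence at the centromere, which lowers the rest of the arm, it was 10.0 ± 5.78, 17.0 ± 5.65 and 15.0 ± 3.41 points, again with 5 of 5 arms higher. Next to the centromere the last 1570 kb of 3L, the first 1567 kb of 2R and the last 855.8 kb of 2L held no cluster in any list. X and 3R had no such long stretch. The centromere-proximal megabase of the arm sequence was covered to 1.79% in replicate 1 and 6.96% in replicate 2 on X, below the rest of that arm. On 3R it was covered to 17.8% and 38.0%. The release also holds heterochromatic sequence apart from the arms, such as 3RHet (2517507 bp, with 0 clusters in each replicate and 2 in the set). How near each arm sequence comes to its centromere was not analysed here, so the arms cannot be compared on this. An exact sign-flip test over the 5 arms, chosen after the data were seen, gave p = 0.0625 for each list with or without the cluster-free sequence, which is the smallest p that 5 arms allow and cannot reach 0.05.

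**Figure D4:**
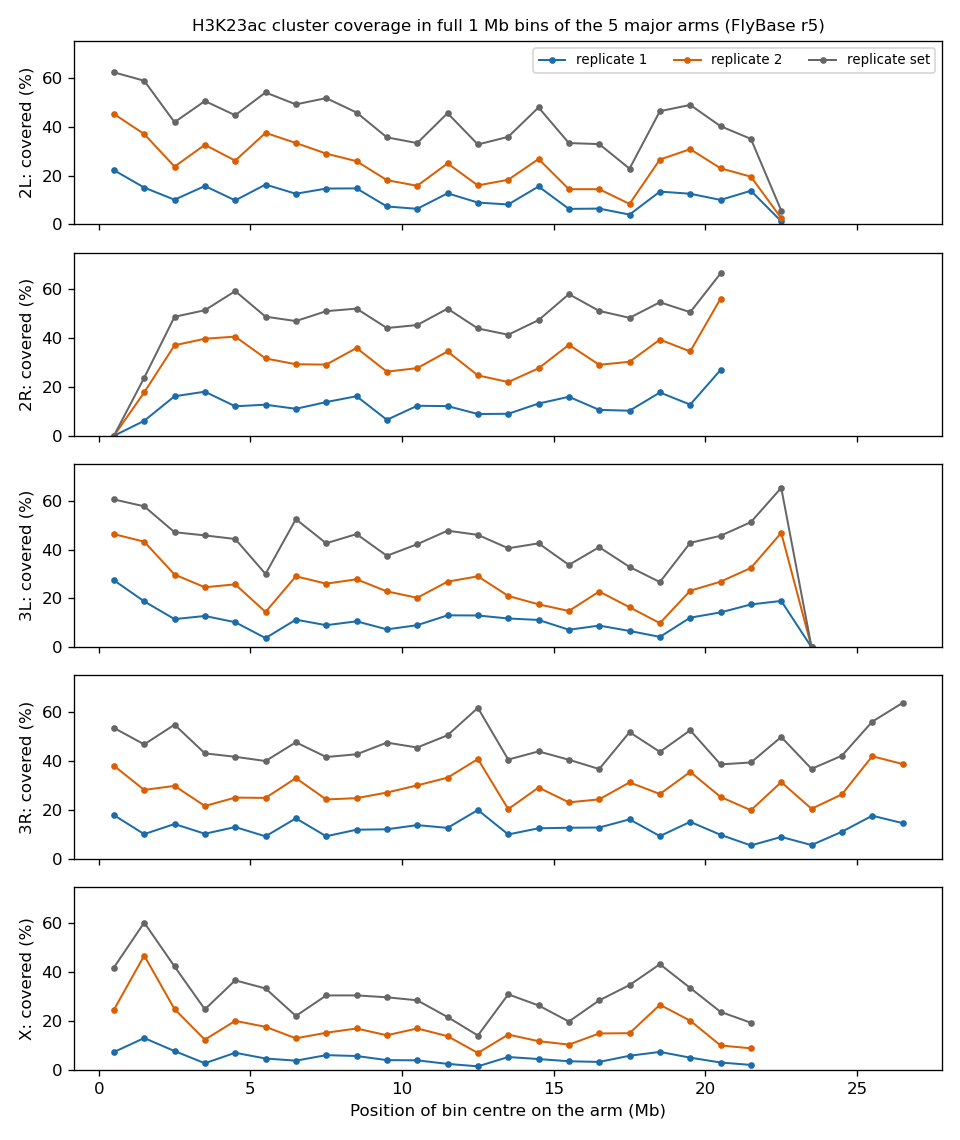
Share of each full 1 Mb bin covered by H3K23ac clusters (y axis, percent) against the position of the bin's centre (x axis, Mb, FlyBase release 5) on 2L, 2R, 3L, 3R and X, one line for each replicate and for the replicate set. The lines rise and fall together, with peaks near the telomeres of 2L, 2R and 3L, a further peak on 3L from 22000001 to 23000000 (65.3% in the replicate set), and coverage of 0 in the centromere-proximal bins of 2R and 3L.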

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

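Some alternatives were chosen after the data were seen: the autosomal arms or X alone, a score of at least 0.6 and a width of at least 3000 bp. The circular shifts behind shared and replicate-only clusters were also chosen then. The others were planned. Of 45 alternative values for 12 results, 39 kept the direction and, where there was a test, its side of the threshold, or moved by less than 1 SD between replicates or the binomial interval, 5 moved further and 1 reversed. With 2 replicates, leaving 1 out always moves a mean by less than 1 SD, so those alternatives could not count as moved. Keeping the major arms only left 6250 of 6267 clusters in replicate 1 and 11742 of 11757 in replicate 2, so it could change little. All overlap, score and width results stayed on their side of the threshold under the alternatives run for them. Requiring 50% of the replicate set's cluster to be covered lowered its share found in both replicates from 21.8% to 10.9% and in either from 60.7% to 55.9%, by construction, since the rule is stricter. The mean ratio of X to autosomal coverage was 0.525. It was 0.764 in the better-scored 50% of each list, and 0.695 in the replicate set. Counted as clusters per Mb it was 0.586, which became 0.323 for clusters at least 3000 bp wide and reversed to 1.47 for clusters with a score of at least 0.6, where X clusters, whose scores were higher, made up more of those left. Why X scores were higher was not settled by these alternatives. Leaving out each replicate in turn gave 0.422 to 0.627 for X and 0.0501 to 0.155 for chromosome 4, where the ratio without replicate 1 was 0.0501. No paired analysis was possible because the input libraries, which share replicate numbers with the ChIP libraries, have no cluster list used here. They could enter only through the authors' calls. Promoter, gene feature and gene list results and their alternatives were not run for want of an annotation of the deposited build used here. Depth is unknown, so how far it limits the shorter list of replicate 1 was not assessed.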

Other observations

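The tests of fewer reads on X, of few reads behind the highest scores and of the width minimum, and all matching on score or width, were chosen after the results were seen. The test of reads near the telomeres was chosen before its result was seen, although the telomere pattern itself was found in these data.

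Long stretches without H3K23ac clusters inside the arms were rare and lay mostly on X. Between neighbouring clusters of any list the median stretch was 1.45 kb, and 9 stretches inside the arms reached 100 kb, of which 6 were on X. The longest was X 21500603 to 21850114 (349.5 kb), followed by 2L 21394848 to 21578533 (183.7 kb), 2R 2229661 to 2389710 (160.1 kb), 2L 10197751 to 10323395 (125.6 kb) and X 14184233 to 14301537 (117.3 kb). How well short reads map to these stretches was not analysed here.

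Among the 3 highest scores of each replicate, 1 cluster of replicate 1 and 2 clusters of replicate 2 had no counterpart in the other. In replicate 1 it was X 13831577 to 13832893 (score 1.15), the highest score of that list. In replicate 2 they were 3R 3528576 to 3529971 (score 3.17) and 3L 6034378 to 6035748 (score 2.87), and the latter was also absent from the replicate set. The median lowest-terms denominator behind the scores was 59.4 per kb of cluster on the autosomal arms in replicate 1 and 65.9 in replicate 2. Their sum of 125.3 lay beside 126.0 in the replicate set. Replicate 2 exceeded replicate 1 by 1.11-fold in this measure and by 1.88-fold in clusters. The denominators are lower bounds from different sets of called clusters and leave out the number that was divided. They therefore do not give the depth of the libraries. On chromosome 4 the denominator per kb relative to the autosomal arms was 1.14 in replicate 1 (bootstrap 95% interval 0.588 to 1.88) and 0.932 in replicate 2 (0.230 to 1.49), and 1.15 in the replicate set (1.06 to 2.01).

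X had fewer clusters per Mb than the autosomal arms but higher scores. A candidate explanation is a lower number of reads on X, with which a region needs a higher ratio to pass a significance threshold; in clusters under 2000 bp wide the denominator per kb on X was 0.741 times that on the autosomal arms in replicate 1 and 0.693 times in replicate 2, but the denominator divides the score, so higher scores alone lower it. At matched score the ratio was 0.834 in replicate 1 (bootstrap 95% interval 0.756 to 1.04), lower on X in 4 of 6 score classes, and 0.787 in replicate 2 (0.748 to 0.840), lower in 8 of 8, a mean of 0.810. In the replicate set, which is not independent of them, it was 0.836 (0.748 to 0.968), lower in 3 of 3, and the explanation stays open because the interval of replicate 1 includes 1. The sex of the larvae, which sets the number of X copies, is not given in the sources used here, and no biological explanation was tested.

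Coverage by H3K23ac clusters was higher in the telomere-proximal megabase than in the rest of the arm on 5 of 5 arms. More reads near the telomeres could lower the ratio needed for a call. For this explanation the denominator per kb there was required, before the result was seen, to exceed 1.2 times that of the rest in both replicates. An interval wholly below 1.2 in both replicates was set then to count against it. On the autosomal arms it was 1.06 times in replicate 1 (bootstrap 95% interval 1.005 to 1.13) and 1.01 times in replicate 2 (0.956 to 1.07), a mean of 1.03. That bound left out the score, whose median in replicate 2 was 0.58 near the telomeres and 0.54 elsewhere, and at matched score and width the ratio was 0.965 (0.873 to 1.13) in replicate 1 and 1.03 (0.899 to 1.35) in replicate 2. In replicate 1 both intervals lay below 1.2, but the first lay above 1, so a smaller excess of reads is not excluded. In replicate 2 the interval at matched score and width includes 1.2. The unmatched intervals of both replicates thus met the rule set beforehand against the explanation. The matched comparison was chosen afterwards and rests on 222 and 169 clusters near the telomeres. It does not exclude the explanation in replicate 2, which therefore stays open. No biological explanation was tested.

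Of the 31 clusters of the replicate set with scores of at least 1, 1 had a counterpart in either replicate. The ratios behind these 31 scores had a median denominator of 3, against 247 for the other clusters, so these scores may rest on few reads in the divisor, although a high ratio by itself favours a small divisor. A higher width minimum in the replicate lists also remains open for the narrow ones: 0 of 26 narrower than 1301 bp (exact interval 0 to 13.2%) and 11.4% of the 4084 others of that width (10.5 to 12.4) had a counterpart. For the 5 wider ones, of which 1 had a counterpart, other clusters within 10% of their width had one in 59.8%, and the exact one-sided probability of finding as few was p = 0.0850, so 5 clusters do not decide it. No biological explanation was tested for these clusters.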
